A study of Mus musculus with 2 samples.

How the data were processed

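Limb tissue of mouse embryos (strain B6NCrl, both sexes pooled) at 15.5 days was assayed by ChIP-seq with an antibody against H3K27ac in 2 biological replicates, made from 78 and 62 embryos. Library fragments were selected at 300 to 500 bp, per the labels. Both replicates form 1 group, with replicate numbers taken from the labels. No group was compared with another, and no batch is named in the labels.

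The files are 4 lists of narrow peaks on mm10, per the labels and the deposited file descriptions. Each replicate's list was derived from its own filtered alignments and 2 control files. The pooled list was derived from the alignments of both replicates and their controls, and the replicated list from both replicates' lists and the pooled list. The aligner, the peak caller, its threshold and the rule for keeping a replicated peak are not given in the sources used here. Tested on the files, 100% of the replicated peaks were entries of the pooled list, 88.8% overlapped both replicates' lists, 11.0% (7311) overlapped 1 of them and 107 overlapped neither. The replicated list is therefore not independent of pooling.

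The deposited signal value of each peak is treated as a score, because the sources do not state that it is a fold over control. It is the authors' own value per peak and was used to describe, rank or filter peaks within a list. The deposited lists also give −log10 p and −log10 q per peak by the authors. The lowest −log10 p was between 2.00 and 2.09 in the 4 lists. The q-value exceeded 0.05 for 11.8% of peaks in replicate 1, 14.3% in replicate 2, 4.31% in the pooled list and 0.263% in the replicated list, so the replicates' lists hold weak peaks by construction. The lists hold no read counts, so depth is unknown and values could not be weighted by it. Wilson 95% intervals on shares of peaks or genes cover counting error only. The 2 replicates give an SD from 2 values, which limits the precision of every mean ± SD.

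Gene models were the basic set of GENCODE M21 on GRCm38, the assembly that mm10 names, with 21851 protein-coding genes on the assembled chromosomes and the TSSs of their protein-coding transcripts. No peak ended beyond a chromosome of the RefSeq copy of this assembly, which also gave lengths and sequence. Peaks on unplaced scaffolds were left out. Overlap was at least 1 bp. Location was assigned at the peak midpoint in the order promoter (within 1 kb of a TSS), exon, intron and other. A gene had a promoter peak when a peak overlapped the 1 kb on either side of any of its TSSs. Acetylated length was the number of bases covered by peaks in the gene and 25 kb on either side, tested as log2(bp + 100), which understates differences between genes with little acetylation. Windows can include acetylation of neighbouring genes.

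Before the data were examined, 23 gene lists were fixed for limb patterning, Hox genes, cell types of the limb, other organs and reference sets. Of the 16 erythroid genes, 15 were in the annotation, and Tbx3 was in 2 lists. Promoter peaks were tested by two-sided Fisher's exact test of members against all other protein-coding genes. Acetylated length was tested by a two-sided permutation test against 100000 random lists of the same size, matched on decile of window length, for which 1e-05 is the smallest p. Both used Benjamini-Hochberg adjustment over the lists, with a threshold of 0.05. Genes are not biological replicates, and these tests describe lists of genes within this group. Shuffles of peak positions within chromosomes numbered 100, and broad regions joined peaks within 12.5 kb.

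The genes named were fixed by rule before the data were examined. They were the Hox genes, Tbx5, Tbx4, Pitx1, Shh, Gli3 and Lmbr1, up to 3 members per list with the most acetylated sequence, up to 3 members of other-organ lists with a promoter peak, up to 5 members of each limb list without one, and the 20 genes and 20 regions with the most acetylated sequence. Genes and regions were ranked by acetylated sequence in the replicated list, while values given with an SD are means of the 2 replicates. Other genes in the text, such as Runx2, Sp7, Myod1, Myf5, Myog and Myl4, were chosen after their values were seen.

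The alternatives were a stricter overlap, a −log10 q of at least 5, a signal value of at least 4, the pooled list, each replicate's own list, promoter windows of 2.5 kb and 250 bp, the 5′-most TSS, a background without receptor families, other flanks, a pseudocount of 1000 bp, no matching, promoters left out and joining within 5 kb. A result given without 1 replicate used the other replicate's own list, which is longer than the replicated list and holds more weak peaks. The signal filter had been planned as a filter on fold enrichment and was applied to the signal value. All annotated coding transcripts and 1 gene per 100 kb were added after seeing the data. Interval arithmetic was tested against a brute-force count with 0 mismatches. On simulated lists of 20 genes drawn from the 21851 genes, the length test gave p below 0.05 for 5.5% of 200 lists with no effect and 76.0% of lists raised by 1.5 on the log2 scale. The Fisher test did so for 6.0% with no effect and 70.5% with 4 times the odds. The simulated genes were drawn at random, so this check does not cover lists of neighbouring genes. For the closing values, the CpG ratio of a promoter was the observed over expected CpG count within 500 bp of the 5′-most TSS. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.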

Results

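H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was mapped by ChIP-seq in limb tissue of mouse embryos at 15.5 days. The labels give 1 group with 2 biological replicates, each a pool of limbs of both sexes. Replicate 1 came from 78 embryos and replicate 2 from 62 embryos. No second tissue, stage or treatment was analysed, so the comparisons were between the replicates, between classes of peaks and between lists of genes. The deposited values were peak lists on mm10 with 115583 peaks for replicate 1, 131076 for replicate 2, 134536 for the 2 replicates pooled and 66530 in the list of replicated peaks. Read depth is unknown, because the lists hold no read counts. The replicated peaks on the assembled chromosomes covered 54.5 Mb, or 2.00% of them, and their median width was 550 bp.

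The first comparison asked how far the 2 replicates marked the same places. Of the peaks of replicate 1, 60.7% (70177 of 115573) overlapped a peak of replicate 2, and 52.7% (69128 of 131067) of those of replicate 2 overlapped one of replicate 1. The mean was 56.7% ± 5.64 (SD, n = 2). Shuffling the peaks of replicate 2 within their chromosomes gave an overlap of 4.69% ± 0.064 (SD over 100 shuffles). Sharing rose with the authors' signal value of the peak: 98.5% of the strongest 20% of peaks of replicate 1 and 96.9% of those of replicate 2 were shared, against 35.7% and 26.8% of the weakest 20%. The shared share was 33.6% when each peak had to cover 50% of the other.

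**Figure D1:**
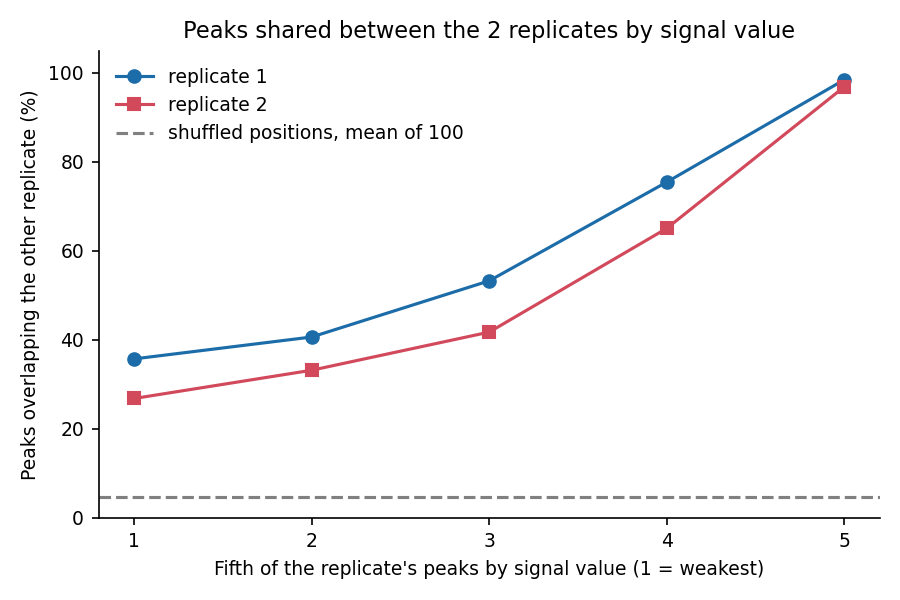
Share of each replicate's peaks (y axis, percent) that overlap the other replicate's list by at least 1 bp, in 5 equal classes of the replicate's own peaks by signal value (x axis). Circles are replicate 1, squares replicate 2, and the dashed line is the mean of 100 shuffles, 4.69%. Both replicates rise from the weakest class (35.7% and 26.8%) to the strongest (98.5% and 96.9%).

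Acetylation lay mostly away from promoters, while promoters were the class most enriched over their share of the genome. Of 66522 replicated peaks, 21.7% (Wilson 95% interval 21.42 to 22.04%) had their midpoint within 1 kb of a protein-coding transcription start site (TSS), 11.0 times the 1.97% of the genome that such windows cover. Introns held 42.7%, exons 3.31% and sequence outside genes 32.3%. The median distance to the nearest TSS was 18.4 kb, and 15.3% of the peaks (10158) lay more than 100 kb from one. Promoter peaks were wider (median 886 bp) and had a higher signal value (median 7.43) than intronic peaks (494 bp and 3.40) or those outside genes (507 bp and 3.54). In the replicates' own lists the promoter share was 15.2% ± 1.09 (SD, n = 2), and among replicated peaks with a signal value of at least 4 it was 41.4%.

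Promoter peaks were over-represented among the peaks that both replicates shared. In replicate 1, 23.1% of shared peaks and 5.06% of unshared peaks lay at promoters, with an odds ratio of 5.63. The corresponding shares in replicate 2 were 22.7% and 5.27%, with an odds ratio of 5.28. Both p-values were below 1e-300 in two-sided Fisher's exact tests, which compare classes of peaks within these libraries, since peaks are not biological replicates. Promoter peaks were also wider and stronger, and sharing rose with signal value. The tests did not adjust for width or strength, so whether location itself matters was not tested.

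The next comparison asked which genes carried an active promoter mark. A replicated peak lay within 1 kb of a TSS in 12037 of 21851 protein-coding genes (55.1%), against 12549 genes with the peaks of replicate 1 alone and 12813 with those of replicate 2. Among 23 gene lists chosen before the data were examined, 7 exceeded all other genes in two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, 8 fell below them and 8 did not pass. All 32 ribosomal protein genes had a promoter peak (adjusted exact p = 6.18e-08), as did the 10 genes of HoxA and HoxD groups 8 to 13, which pattern the limb along its axis (adjusted p = 0.00577). The share was 90% (18 of 20) for fibroblast genes (adjusted exact p = 0.00279), 86.2% (25 of 29) for chondrocyte genes and 82.1% (32 of 39) for limb patterning genes (both adjusted p = 0.00159). For tendon and joint genes it was 83.3% (15 of 18, adjusted exact p = 0.0279), and for epidermal genes 90.9% (20 of 22, adjusted p = 0.00159). In the replicates' own lists these shares were 92.5% ± 3.54 for fibroblast, 91.4% ± 2.44 for chondrocyte, 82.1% ± 3.63 for limb patterning, 83.3% in each replicate for tendon and joint, and 97.7% ± 3.21 for epidermal genes (SD, n = 2). The HoxA and HoxD genes lie in 2 loci, and with 1 gene per locus the share stayed at 100% but 2 genes were too few to pass (adjusted exact p = 0.581). The tendon and joint call ended without replicate 1 (adjusted exact p = 0.0706) and without receptor genes in the background (adjusted p = 0.0749), and among peaks with a signal value of at least 4 the epidermal share was 36.4% and did not pass (adjusted p = 0.334).

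**Figure D2:**
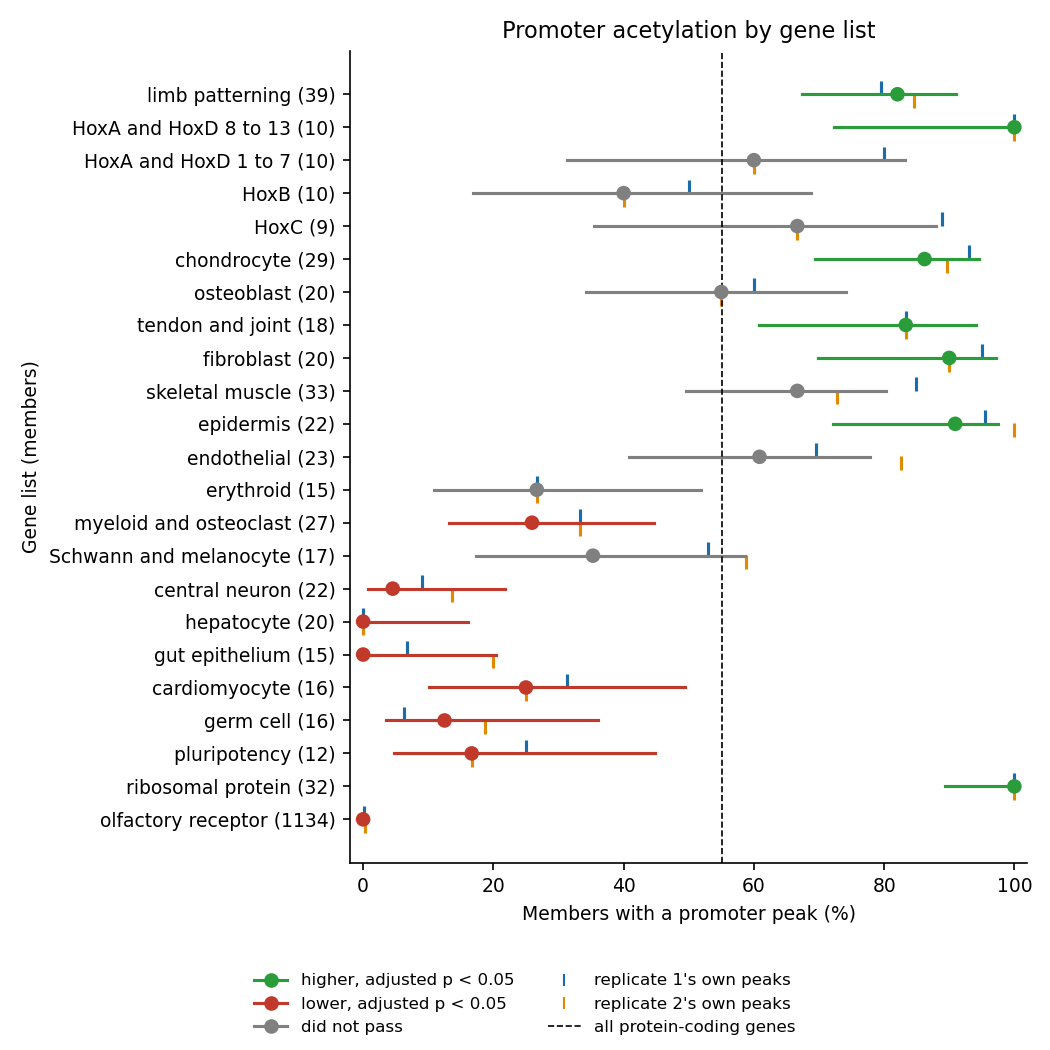
Percent of each list's members with a replicated peak within 1 kb of a TSS (x axis), one gene list per line with its number of members. Circles with bars are the share and its Wilson 95% interval, ticks above and below the bar are the shares from replicate 1's and replicate 2's own peaks, colours give the adjusted Fisher's exact test and the dashed line marks all protein-coding genes (55.1%). Limb patterning, HoxA and HoxD 8 to 13, chondrocyte, tendon and joint, fibroblast, epidermal and ribosomal lists pass to the right of the line, HoxB lies to its left, and hepatocyte, gut and olfactory receptor lists lie at 0.

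Lists for organs other than the limb fell below other genes. None of 20 hepatocyte genes (Wilson 95% interval 0 to 16.1%, adjusted exact p = 8.46e-07), none of 15 gut epithelial genes (0 to 20.4%, adjusted p = 2.79e-05) and none of 1134 olfactory receptor genes (0 to 0.338%, adjusted p below 1e-300) had a replicated promoter peak. In the replicates' own lists, the gut share was 13.3% ± 9.43 and the olfactory share 0.221% ± 0.0624, while the hepatocyte share was 0 in both (SD, n = 2). Of 22 central neuron genes only Elavl4, an RNA-binding protein of neurons, had a replicated promoter peak (4.55%, adjusted exact p = 3.58e-06). The central neuron share was 9.09% with the peaks of replicate 1 and 13.6% with those of replicate 2. Germ cell genes had 2 of 16 (Dazl, and Sohlh1, which had none in replicate 1, adjusted exact p = 0.00159) and pluripotency genes 2 of 12, namely Esrrb and Tbx3, the latter also a member of the limb patterning list (adjusted p = 0.0151). The 4 of 16 cardiomyocyte genes with a peak were Myh7, Tnnt2, Myl3 and Myl4, sarcomere genes that skeletal muscle also uses at some stages (adjusted exact p = 0.0328). Without replicate 2 the pluripotency (adjusted exact p = 0.0527) and cardiomyocyte (adjusted p = 0.0576) calls ended.

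Among lists for cell types of vessels, blood, nerve, bone and muscle, 1 passed. Myeloid and osteoclast genes fell below other genes, with 7 of 27 (25.9%, adjusted exact p = 0.00577), among them Nfatc1, a regulator of osteoclast formation, and Cd68. The osteoblast share was 55.0% (11 of 20, adjusted exact p = 1.0), the skeletal muscle share 66.7% (22 of 33, adjusted p = 0.282), the endothelial share 60.9% (14 of 23, adjusted p = 0.779), the Schwann cell and melanocyte share 35.3% (6 of 17, adjusted p = 0.192) and the erythroid share 26.7% (4 of 15, adjusted p = 0.0515). The Schwann cell and melanocyte share was 52.9% with the peaks of replicate 1 and 58.8% with those of replicate 2, against 57.4% and 58.6% of all protein-coding genes. In the osteoblast list the bone regulators Runx2 and Sp7 and the matrix and mineral genes Col1a1, Col1a2, Sparc and Ifitm5 had promoter peaks, and the matrix and mineral genes Alpl, Ibsp, Spp1, Bglap and Bglap2 had none. In the muscle list the regulators Myod1, Myf5 and Myog and the sarcomere genes Tnnt3, Tnni1, Tnnc2, Mylpf, Myh3, Myl1 and Neb had promoter peaks in the replicated list. Such a peak need not be present in each replicate's own list. The regulators Myf6 and Pax3 and the sarcomere genes Acta1, Actc1 and Myh8 had no replicated one, though Acta1 had one in replicate 1. Skeletal muscle passed as higher with the pooled peaks (87.9%, adjusted exact p = 0.00144) and without replicate 2 (84.8%, adjusted p = 0.00275), and as lower with a signal value of at least 4 (21.2%, adjusted p = 0.00265). Endothelial genes did likewise with the pooled peaks (82.6%, adjusted exact p = 0.0401), without replicate 1 (82.6%, adjusted p = 0.0282) and with a signal value of at least 4 (8.70%, adjusted p = 0.000287). The erythroid list missed the threshold narrowly and passed as lower in 8 of its 11 alternatives (adjusted exact p from 0.00537 to 0.0479), among them those without replicate 2 (0.0311) and without replicate 1 (0.0250), so its call depends on the setting.

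The extent of acetylation around genes was then compared, as the length covered by replicated peaks in the gene and 25 kb on either side. Over all protein-coding genes the median was 2.13 kb, and 26.3% of genes had none. The HoxA and HoxD genes of groups 8 to 13 stood furthest above random lists matched on window length, with a median of 37.8 kb and a mean log2 difference of 5.41. The difference was 3.27 for HoxA and HoxD groups 1 to 7 (median 13.6 kb) and 2.68 for HoxC (7.69 kb), while HoxB was at 0.78 (1.96 kb) and did not pass (adjusted permutation p = 0.421). Chondrocyte genes were higher by 2.33 (8.01 kb), tendon and joint genes by 2.24 (8.24 kb), fibroblast genes by 2.09 (10.3 kb), epidermal genes by 1.89 (5.80 kb), limb patterning genes by 1.36 (5.30 kb) and ribosomal protein genes by 2.58 (4.04 kb). Olfactory receptor genes (−2.94), central neuron genes (−2.33) and hepatocyte genes (−1.47, adjusted permutation p = 0.0141) were lower. These 9 higher and 3 lower lists passed two-sided permutation tests against 100000 random lists with Benjamini-Hochberg adjustment. Both HoxA and HoxD lists and the chondrocyte, ribosomal and olfactory lists had a permutation p of 1e-05, the smallest the draws can give, and an adjusted p of 4.6e-05. Windows of neighbouring genes overlap, so the p-values of clustered lists count the same sequence more than once. Each HoxA and HoxD list lies in 2 loci, HoxC in 1 and the olfactory list in 269. The adjusted permutation p was 7.67e-05 for central neuron, 0.000345 for tendon and joint and for fibroblast, 0.000792 for epidermal, 0.000966 for limb patterning and 0.00219 for HoxC genes. The lists that did not pass were osteoblast (1.103, adjusted permutation p = 0.0857), skeletal muscle (0.80, 0.0993), erythroid (−1.27, 0.0781), myeloid and osteoclast (−0.76, 0.165), Schwann cell and melanocyte (−0.90, 0.171), gut epithelium (−0.96, 0.171), pluripotency (−0.97, 0.249), endothelial (0.39, 0.486), germ cell (−0.41, 0.549) and cardiomyocyte genes (−0.33, 0.603). With 1 gene per 100 kb, the difference of HoxA and HoxD groups 1 to 7 fell to 0.33 on 2 genes (adjusted permutation p = 0.833), that of HoxC to 1.72 on 1 gene (0.544) and that of hepatocyte genes moved to −1.13 on 16 genes (0.142), so these calls ended with smaller differences and fewer genes. The gene kept was the first in list order, Hoxa1 (4.50 kb) and Hoxd1 (0 kb) for groups 1 to 7 and Hoxc4 (5.16 kb) for HoxC. Replicated peaks covered up to 32.4 kb at Hoxa7, and from 1.84 kb at Hoxc13 to 12.4 kb at Hoxc5, whose annotated model spans neighbouring Hox genes. The size of both Hox falls therefore depends on the gene kept. The HoxA and HoxD groups 1 to 7 call also ended with the gene body alone, at a difference of 1.08 (adjusted permutation p = 0.0568). On that measure groups 8 to 13 stayed at 3.72. Windows of some genes of groups 1 to 7 take in genes of groups 8 to 13, as that of Hoxa7 does with Hoxa9 and Hoxa10. Part of their acetylated length therefore belongs to those neighbours. The hepatocyte call ended with 100 kb on either side (0.792) and the epidermal call with a signal value of at least 4 (0.128). Osteoblast genes passed as higher in 5 of 11 alternatives (adjusted permutation p from 0.00364 to 0.0481), 1 of them without replicate 2 (1.20, 0.0481). Erythroid genes passed as lower in 4 of 11 (0.0128 to 0.0455), skeletal muscle genes as higher with the pooled peaks (0.0307), and gut, cardiomyocyte and germ cell genes as lower with the gene body alone (0.000272, 0.00215 and 0.00315).

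**Figure D3:**
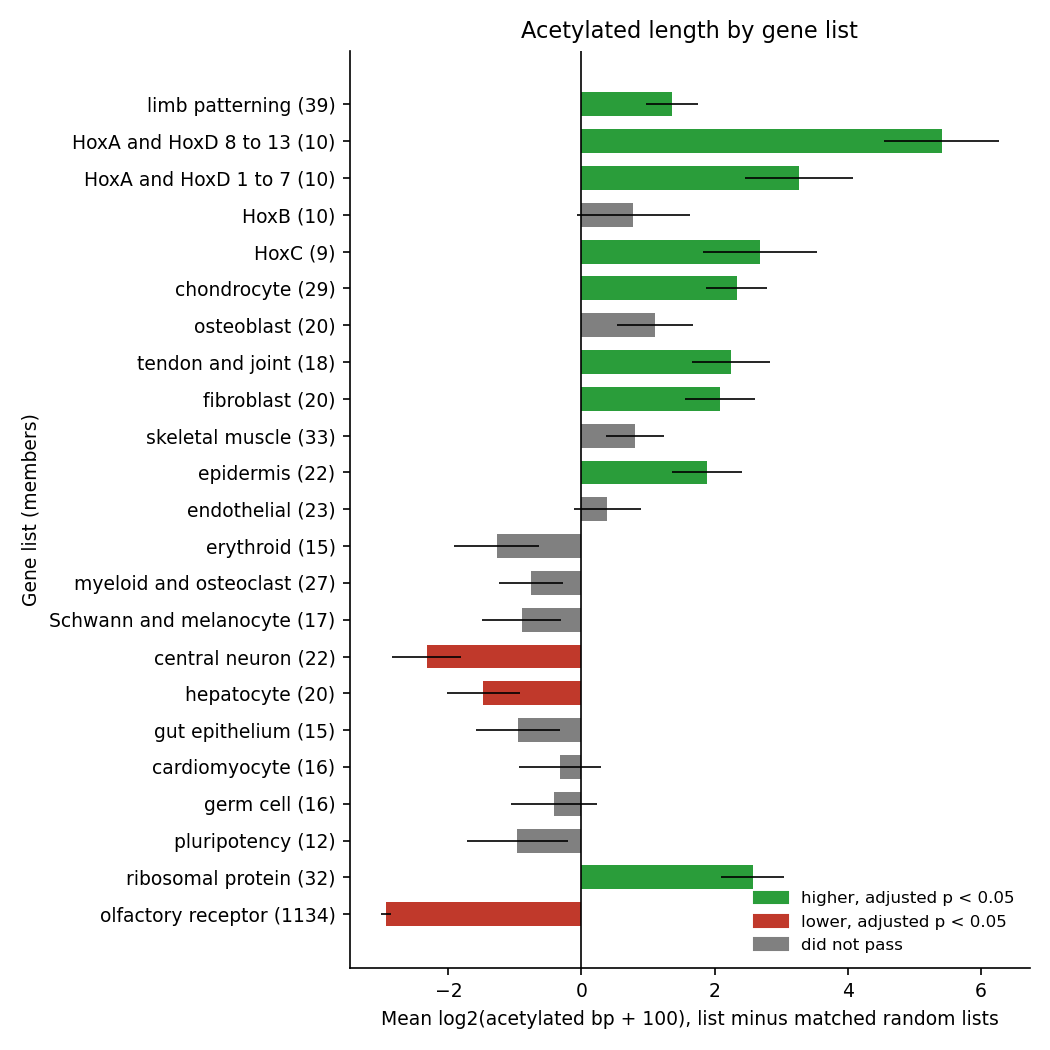
Difference in mean log2(acetylated bp + 100) between each gene list and 100000 random lists matched on window length (x axis), one list per bar with its number of members. Error bars are the SD of the random lists' means, and colours give the adjusted permutation test. HoxA and HoxD genes of groups 8 to 13 reach 5.41, and olfactory receptor genes lie at −2.94.

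Within the Hox clusters, which hold homeobox regulators of body position, acetylation was concentrated in HoxA and HoxD. Replicated peaks covered 44.7% of the HoxA cluster (chromosome 6, 52155590 to 52260880) and 30.2% of HoxD (chromosome 2, 74668310 to 74765142), against 11.8% of HoxC (chromosome 15, 102921103 to 103036852) and 3.00% of HoxB (chromosome 11, 96194316 to 96368256). The replicates' own peaks gave 42.5% ± 0.412, 28.6% ± 1.54, 11.1% ± 0.384 and 3.38% ± 0.763 (SD, n = 2), so that the clusters differed by more than the spread between replicates. Along HoxA the gene body of Hoxa9 was 98.2% covered, Hoxa10 90.7%, Hoxa11 96.0%, Hoxa7 62.3% and Hoxa13 60.9%. The others had 22.7% for Hoxa4, 19.3% for Hoxa2, 14.3% for Hoxa3, 12.53% for Hoxa6 and 0 for Hoxa5 and Hoxa1. Along HoxD, Hoxd12 was 97.5% covered, Hoxd11 84.2%, Hoxd10 81.8%, Hoxd9 61.9%, Hoxd13 57.3% and Hoxd8 52.3%. Hoxd4 was at 6.72%, Hoxd3 at 3.18% and Hoxd1 at 0. Promoter peaks were present at 9 of 11 HoxA, 7 of 9 HoxD, 6 of 9 HoxC and 4 of 10 HoxB genes. The annotated models of Hoxa3, Hoxc5 and Hoxd3 span neighbouring Hox genes. A promoter peak or covered share given for these genes can therefore belong to a neighbour. As lists, HoxA and HoxD groups 1 to 7 (6 of 10, adjusted p = 1.0), HoxB (adjusted p = 0.436) and HoxC (adjusted p = 0.810) did not pass Fisher's exact test against other genes, though HoxB passed as lower with a signal value of at least 4 (adjusted p = 0.0281).

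**Figure D4:**
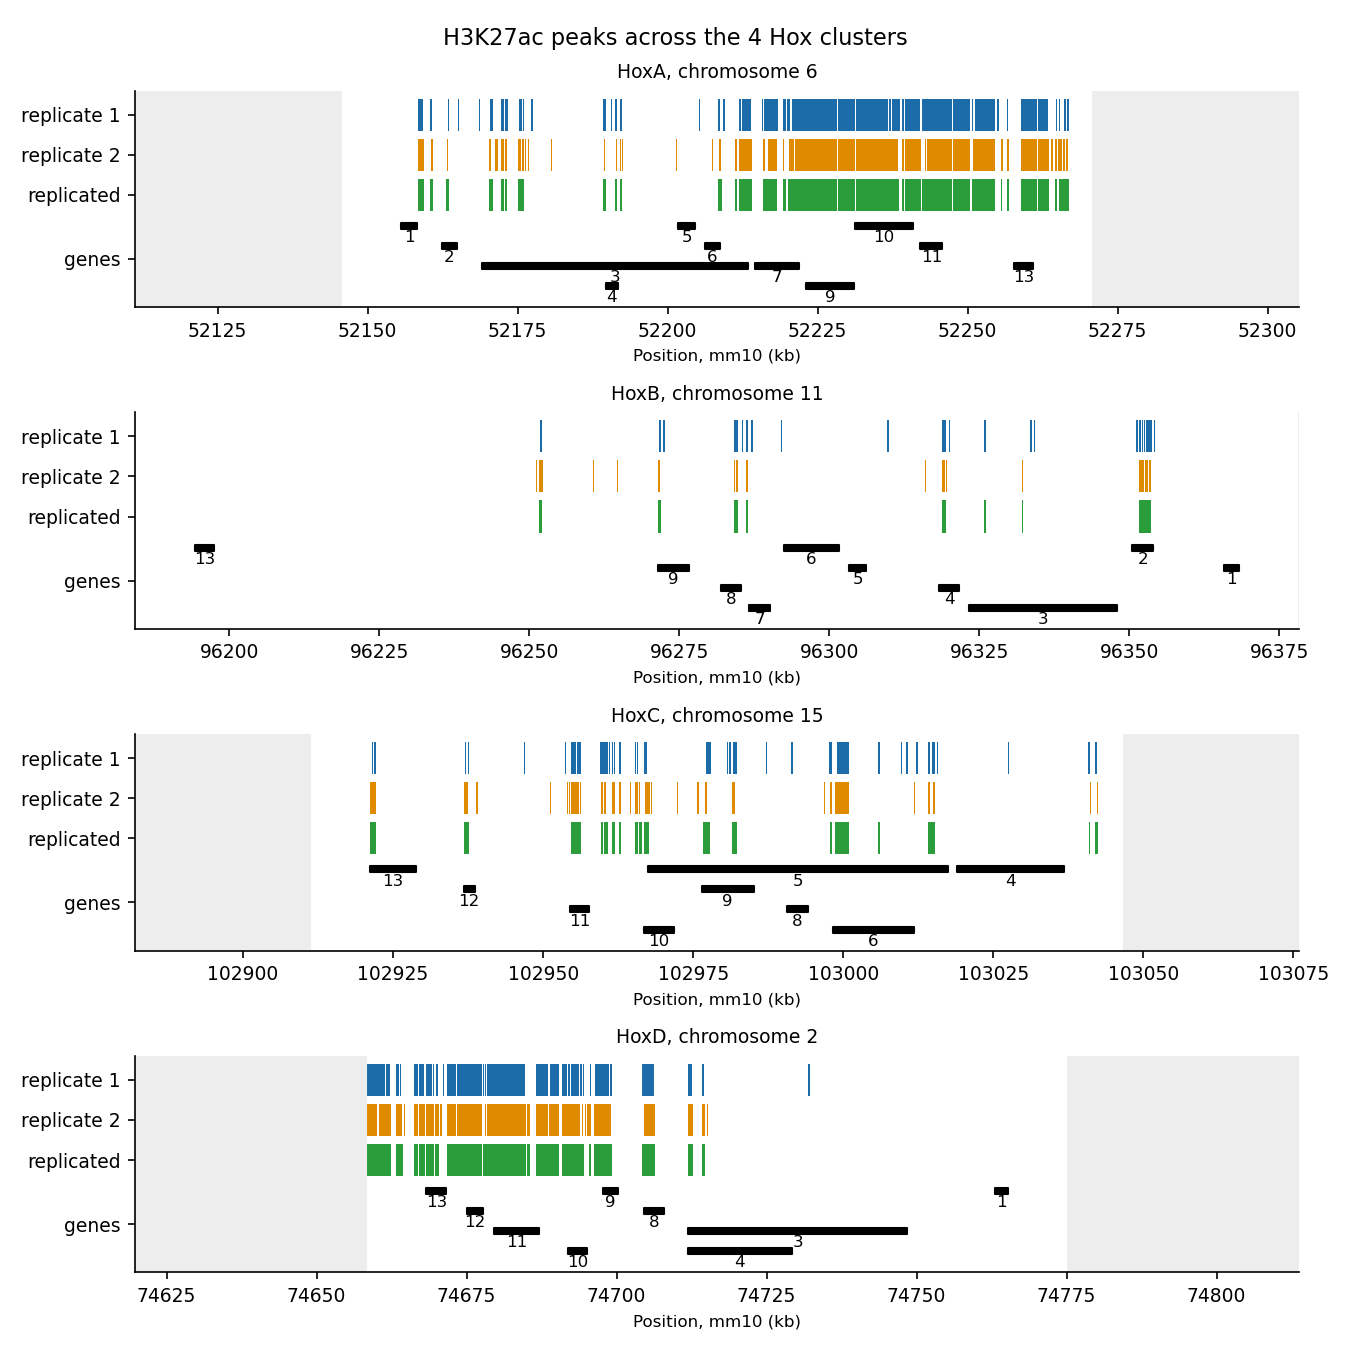
Maps of the 4 Hox clusters drawn to one scale (x axis, mm10 position in kb), with peaks of replicate 1, replicate 2 and the replicated list as coloured blocks and Hox gene models as black bars numbered by group. Peaks are drawn up to 10 kb beyond each cluster, and the grey areas lie outside that range. Blocks fill most of the span from Hoxa9 to Hoxa13 and from Hoxd9 to Hoxd13, where 44.7% of HoxA and 30.2% of HoxD are covered in all.

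Regulators of limb identity and patterning were marked in both replicates. Tbx5, which specifies the forelimb, had 22.3 kb ± 2.22 of acetylated sequence (SD, n = 2), and Tbx4 and Pitx1, which act in the hindlimb, had 16.9 kb ± 1.72 and 6.14 kb ± 1.30. Each of these 3 genes had a promoter peak in both replicates. Gli3, a transcription factor of the Hedgehog pathway, had 27.1 kb ± 4.51, and Prrx2, a homeobox gene of limb mesenchyme, had 28.7 kb ± 2.48. Shh, the signal of the early posterior limb bud, had no peak within 25 kb in either replicate. Lmbr1, whose introns host the limb enhancer of Shh, had 2.32 kb ± 0.035, and the 2 replicated peaks inside it were at its promoter and within an intron (chromosome 5, 29366931 to 29367315). The position of the enhancer was not used, so whether the intronic peak lies at it was not tested. Fgf8 and Fgf4, signals of the apical ridge of the early limb bud, had 0.647 kb ± 0.328 and 0.180 kb ± 0.004, and neither they nor Wnt7a, Sall3 or Shh had a replicated promoter peak, though Wnt7a had one in replicate 2.

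Members of the cartilage, tendon and fibroblast lists were among the genes with long acetylated sequence, as were some members of the osteoblast list, which as a whole did not pass. These lengths also depend on gene length. Replicated peaks covered 4.64% of the window of Sox6, 6.35% of Foxp1 and 12.9% of Creb5, against 44.4% of Col2a1 and 54.5% of Col1a1. In the chondrocyte list Wwp2 had 59.9 kb ± 5.14, Col2a1, the main collagen of cartilage, 32.5 kb ± 0.960 and Sox6, a cartilage transcription factor, 31.2 kb ± 5.62 (SD, n = 2). Col10a1 and Ihh, genes of maturing cartilage, had 0.976 kb ± 0.034 and 0.794 kb ± 0.031 and no promoter peak in either replicate or the replicated list. Ucma and Epyc had none in the replicated list. Replicate 1 had one at Ucma, and both replicates had one at Epyc. The collagen genes Col1a1 and Col1a2 had 35.2 kb ± 1.28 and 29.4 kb ± 0.327, and Sparc, a matrix protein of bone, 23.1 kb ± 0.733. Ibsp, Dmp1, Phex, Mmp13 and Bmp8a had none in the replicated list. In the tendon and joint list Creb5 had 55.4 kb ± 7.68, Erg 21.98 kb ± 3.24 and Bgn 16.9 kb ± 0.429. Tnmd, Thbs4 and Prg4 had no promoter peak. Among fibroblast genes Foxp1 had 45.7 kb ± 5.90, Col5a1 41.6 kb ± 1.93 and Fbn2 36.9 kb ± 4.63, and Tcf21 and Mfap5 lacked a replicated promoter peak, though Mfap5 had one in replicate 1.

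Some muscle, epidermal and blood vessel genes also had long acetylated sequence, although the muscle and endothelial lists as a whole did not pass. Of the muscle genes Tnnt3, the fast skeletal troponin T, had 42.9 kb ± 1.48, Mymx, which drives myoblast fusion, 12.6 kb ± 0.001 and Tnni1, the slow troponin I, 12.1 kb ± 0.344 (SD, n = 2). Myh8 had none in the replicated list and Actc1 had 0.327 kb. Of the epidermal genes Itgb4 had 14.2 kb ± 0.917, Cdh3 13.2 kb ± 1.80 and Irf6 11.3 kb ± 0.210. Trp63 and Lamb3 had no promoter peak in the replicated list. Replicate 2 had one at Trp63, and both replicates had one at Lamb3. By acetylated length in the replicated peaks, Fli1 (24.0 kb ± 1.63), Eng (16.8 kb ± 0.304) and Egfl7 (11.6 kb ± 0.039) led the endothelial list, in which Cldn5 had none. On the same measure Nfatc1 (35.3 kb ± 4.08), Cx3cr1 (16.8 kb ± 0.725) and Cd68 (15.6 kb ± 0.351) led the myeloid and osteoclast list. Cd68 spans 1.94 kb, so most of its length lay outside the gene and can belong to neighbouring genes. Cx3cr1 had no promoter peak in either replicate or the replicated list. In the replicated peaks Erbb3 (9.72 kb ± 0.499), Pmel and Ngfr led the Schwann cell and melanocyte list, and Nfe2 (6.69 kb ± 0.974), Tal1 and Ank1 the erythroid list. Some genes of other organs had acetylated sequence in their windows without a promoter peak of their own, such as Lgals4 (16.0 kb ± 1.01), Cdx1 (10.7 kb ± 0.577) and Vil1 (9.996 kb ± 0.168) in the gut list, Myh6 and Tnni3 in the cardiomyocyte list and Prm2 and Prm1 in the germ cell list.

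The 20 genes with the most acetylated sequence across the genome in the replicated list were Gm20388, Fgfr2, Dnm3, 2010111I01Rik, Rad51b, Zmiz1, Nfix, Ncor2, Nfib, Gse1, Sept9, Zfhx3, Tcf4, Sh3pxd2a, Wwp2, Ski, Tns1, Creb5, Frmd4a and Rxra. Their replicate means ran from 330.1 kb ± 7.20 for Gm20388 to 51.6 kb ± 2.41 for Rxra (SD, n = 2). This ranking depends on gene length, since the annotated models of Gm20388 and Fgfr2 span 4435 kb and 2961 kb. Per length of window, Nfix, a transcription factor, had 54.8% covered, Ski, a corepressor, 51.1% and Rxra, a nuclear receptor, 40.9%, against 7.40% for Gm20388 and 6.31% for Fgfr2.

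Joining neighbouring replicated peaks gave 23183 regions, with a median of 1.22 kb covered by peaks, and the 20 with the most held 2.75% of the covered sequence. The first (chromosome 7, 142428313 to 142612348) had 103 kb ± 0.658 covered in the replicates (SD, n = 2) and spanned the muscle genes Tnni2 and Tnnt3 with Syt8, Lsp1 and Mrpl23. The next spanned Ski and its neighbours (chromosome 4, 155054420 to 155308344, 93.0 kb ± 2.35), Nfix (chromosome 8, 84633949 to 84815602, 91.0 kb ± 2.71) and Mest, Copg2 and the Cpa genes (chromosome 6, 30509073 to 30749862, 92.2 kb ± 2.92). Further regions lay at Dnm3 (87.8 kb ± 5.40), Rxra with Col5a1 (84.2 kb ± 2.99), Zmiz1 (73.4 kb ± 1.56), Actn4 with Lgals4 and Capn12 (75.8 kb ± 1.17), Wasf2 with Ahdc1 (62.1 kb ± 1.86), Sept9 (60.2 kb ± 1.04), 2010111I01Rik with Fancc (57.6 kb ± 3.44), Cstad (58.4 kb ± 2.28) and Nxn with Abr (54.7 kb ± 1.41). The remaining ones lay at Irf2bp2, Tns1, Vgll4, Rara, Antxr1 and Nepro, with 45 to 55 kb each, and in a region without a protein-coding gene (chromosome 13, 60241888 to 60489758, 69.4 kb ± 1.55), 64.5 kb from Gas1, which encodes a membrane protein of Hedgehog signalling. Of the 20 regions, 13 overlapped the 20 highest without replicate 2, 10 with a signal value of at least 4 and 11 with joining within 5 kb.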

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

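The comparisons used the assembled chromosomes, and 8 replicated peaks lay outside them, on 5 unplaced or unlocalized scaffolds, above the 3 that a count of 0 allows. Replicate 1 had 10 such peaks and replicate 2 had 9. Their median signal value in the replicated list was 4.85 and the highest 44.7. No explanation was tested for these peaks.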

How the results depend on the processing

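Of the 15 lists called by promoter peaks, 10 kept their direction and their side of the threshold under every alternative run, as did 8 of the 12 called by acetylated length, and the others are named with their values in the results above. Over the 252 alternative values for single lists by promoter peaks, 231 kept their side of the threshold, 13 passed anew in the same direction, 5 no longer passed and 3 turned direction with a test passed before or after. Over the 253 by acetylated length, 234 kept it, 13 passed anew, 6 no longer passed and 0 turned in this sense. Among values that passed neither before nor after, the direction also changed in 18 by promoter peaks and 12 by acetylated length, so the direction of lists that were not called is not stable. The 3 that turned with a passed test were at a signal value of at least 4, where promoter peaks remained for 21.2% of skeletal muscle, 36.4% of epidermal and 8.70% of endothelial genes. The mean share of peaks shared by the replicates was 56.7%, and it was 46.8% with an overlap of 50% of the peak, 33.6% with 50% of both peaks, 75.9% with −log10 q of at least 5 and 74.4% with a signal value of at least 4. The promoter share of 21.7% was 13.6% in the pooled list, 28.1% with −log10 q of at least 5, 41.4% with a signal value of at least 4, 26.4% with a 2.5 kb window and 14.5 to 16.0% in the replicates' own lists, which stand for each replicate left out in turn. Lists lower in acetylated length numbered 7 with the gene body alone against 3. Of the 20 broad regions, 10 overlapped the highest 20 with a signal value of at least 4, 11 with joining within 5 kb and 13 to 15 with each replicate left out. For these shifts the cause was not tested. The odds ratios for promoters among shared peaks stayed between 3.17 and 6.27 under the alternatives run. All annotated coding transcripts and 1 gene per 100 kb were chosen after seeing the data. The unknown depth limits what the absence of a peak shows. No paired analysis was possible because the labels give 1 group.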

Other observations

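On chromosome X the tests of a halved signal outside promoters, of unique sequence outside promoters and of CpG content as the whole cause, and on forelimb and hindlimb genes all tests, were chosen after the results they build on were seen, as were the genes and intervals named here. Among non-coding genes, the imprinted H19, Mir140, a microRNA of cartilage inside Wwp2, the Dnm3os transcript with Mir214 and Mir199a-2, and Hottip and Hoxa11os of the HoxA cluster had a peak within 1 kb of their 5′ end in both replicates and in the replicated list. Replicated peaks covered 98.9% of H19 (chromosome 7, 142575529 to 142578143), which lies in the joined region with the most covered sequence, beside Tnnt3. They covered 88.1% of Dnm3os, 98.0% of Hoxa11os and 57.4% of Hottip. Hotair of the HoxC cluster had such a peak in replicate 1 and none in replicate 2 or the replicated list. Mir206 and Mir133b of muscle, Mir122 of liver and Mir124a-1 and Mir9-2 of brain had none in the 3 lists. For microRNAs the position is the end of a short annotated sequence, so absence there says nothing about a transcript start elsewhere. Replicated peaks covered 0.968 kb around each of Mir206 and Mir133b, 1.82 kb around Mir122, 0.38 kb around Mir9-2 and 0 kb around Mir124a-1. Of 5502 lincRNA genes with their 5′ end more than 1 kb from a protein-coding TSS, 796 (14.5%) had a peak there, against 2.40% of 9886 processed pseudogenes.

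Among 19145 intervals between neighbouring protein-coding genes, 50.9% held no replicated peak sequence. The interval with the most lay between Rps24 and Zmiz1 (chromosome 14, 24496960 to 25459184), with 128 kb ± 7.96 in the replicates (SD, n = 2). Intervals beside Zfp36l2 (88.3 kb ± 3.27) and Zfp36l1 (87.3 kb ± 1.05), both sides of Gas1 (78.8 kb ± 1.79 and 61.5 kb ± 1.22) and the interval between Mrpl23 and Igf2 (39.0 kb ± 1.60), which holds H19, were also among the 20 highest. The 781 kb interval beyond Mtx2, next to HoxD, held 17.9 kb ± 1.65, and the 1705 kb and 457 kb intervals on either side of Sox9, the main regulator of cartilage, held 30.2 kb ± 5.27 and 20.3 kb ± 5.78. The strongest replicated peak by signal value (63.7) lay at chromosome 5, 115488556 to 115491407, outside protein-coding promoters, and the next lay at the promoter of Sp3 (57.7).

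Promoter peaks of epidermal, endothelial and skeletal muscle genes were common but weak. Of the 56 members of the 3 lists with a promoter peak, 17 reached a signal value of 4, and their median was 3.67, against 9.78 for 58 members of the chondrocyte, fibroblast and tendon and joint lists. Matching on CpG content removed part of the difference. The mean log2 signal value was −1.21 from random genes with a promoter peak unmatched and −0.81 from CpG-matched ones (permutation p = 1e-05, the smallest the draws can give). Because the 3 lists had been picked for weak promoter peaks, this p-value is no independent test of CpG content. Whether these cell types make up a smaller share of the tissue stays open. After adjustment for CpG content the 3 lists lay at −1.17 on the log2 scale relative to the chondrocyte, fibroblast and tendon and joint lists, but they had been picked because their promoter peaks were weak, so this value restates the pattern and decides nothing. Lists not picked in this way went apart: against CpG-matched genes the difference was −1.12 for 4 erythroid genes (permutation p = 0.0134), −0.35 for 7 myeloid and osteoclast genes (permutation p = 0.341) and 0.12 for 6 Schwann cell and melanocyte genes (permutation p = 0.759). HoxC genes, which mark no single cell type, were also weak (−1.16, permutation p = 0.00127), and the shares of cells were not measured.

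Chromosome X had few peaks, with 5.67 replicated peaks per Mb against 26.6 on the autosomes, a ratio of 0.213 (exact 95% interval 0.200 to 0.227). The interval covers counting error only, and the replicates' own peaks gave ratios of 0.180 and 0.189, both below it. Among replicated peaks the ratio was 0.143 outside promoters, while the density of protein-coding genes had a ratio of 0.659. Less unique sequence does not account for the whole deficit. Per Mb of sequence that is neither gap nor repeat, the ratio rose to 0.271 for all peaks and 0.181 outside promoters (0.166 to 0.198). Fewer CpG-rich promoters explain part of the deficit at promoters. Of X genes 37.2% had a promoter peak, −18.3 points from random genes and −7.78 points from CpG-matched genes (permutation p = 1e-05), which is within the 10 points set beforehand but still below the matched genes, so CpG content is not the whole cause.

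Whether a lower copy number or fewer active copies of X contribute stays open, because the tests differ. A test written beforehand asked whether a lower copy number of X lowers detection, and it counted against that explanation. Among all peaks with a signal value of at least 8, the ratio was 0.332 (0.288 to 0.380), under the bound of 0.5. After that value was seen, the test was replaced by one of fewer active copies outside promoters. The reasons were that X also has fewer genes per Mb (0.659) and that one limit on both sides cannot show a signal scaled down on X. If X signal outside promoters were halved, X peaks of at least 4 would stand against autosomal peaks of at least 8, and these densities had a ratio of 1.04 (0.896 to 1.21), against 0.229 with 8 on both sides. The halving is an assumed, lenient factor, and this later test may have been favoured by the earlier result. At promoters with a peak, X signal was −0.19 from CpG-matched promoters on the log2 scale (permutation p = 0.00011). The size of this difference lay between the bounds of 0.3 and 0.1 set before it was computed. Only promoters with a peak entered, and X promoters with a lowered signal can be missing from them. The value therefore does not exclude a halving.

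The labels give limb without saying which. The promoters of Tbx4 and Pitx1, hindlimb genes, had 4 of 4 possible peaks over the 2 replicates, and that of Tbx5, a forelimb gene, had 2 of 2. Promoter peaks in both replicates were present at 55.1% of all protein-coding genes, so they decide little. The acetylated length of Tbx5 (22.3 kb ± 2.22) and Tbx4 (16.9 kb ± 1.72, SD, n = 2) lay above the 90th percentile of all genes (10.2 kb), which goes against tissue of a single limb type, while that of Pitx1 (6.14 kb ± 1.30) lay above the median (2.13 kb) only. Without a sample of either limb alone, what these genes would show in the other limb is unknown, so neither forelimb tissue only nor hindlimb tissue only is excluded.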
